A study of Homo sapiens with 12 samples.

How the data were processed

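Illumina HumanHT-12 beadchips of version 3 measured RNA of U87 MG cells and of their exosomes, in 4 groups of 3 replicates (12 arrays). Per the labels' protocols, the experiment ran in high-glucose DMEM with bovine serum albumin, and hypoxic cultures stood in a workstation at 1% oxygen for 48 hours and normoxic ones at 21%. Exosomes were taken from the conditioned medium by differential centrifugation, RNA was extracted with Trizol and treated with DNase, and biotinylated cRNA was made with Illumina's TotalPrep kit. The labels call the 3 samples of each group biological replicates. The p-values of limma measure only the spread between these samples, and Fisher's and the family permutation tests run over genes, which are not independent replicates.

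The deposited value table gives an intensity per probe and array on a linear scale, and the labels state no further transformation. Tested on the table itself, its values reach down to near background level, so that a background appears to have been subtracted, and part of the cells are blank. The quantiles of the listed values are nearly equal over the 6 cell arrays (median 5.02 to 5.08, 99th percentile 4431 to 4538) and over the 6 exosome arrays (median 2.99 to 3.00, 99th percentile 576 to 608). Each material thus appears to have been normalised by itself over listed values. Of 48966 probes, 22375 were blank on some cell arrays and 30848 on some exosome arrays, where their listed values had a median of 2 and a 99th percentile of 6.24 and 5.54, so a blank was read as 0. The tables of unnormalised scanner output, with 24 columns of values, have column names that match no sample label and were not used here, so detection p-values were not used either. The plan made before the data were examined was to background-correct and quantile-normalise those scanner tables with limma's neqc and to filter on detection p. In its place, log2(intensity + 50) of the value table was used with no further normalisation, and probes with a mean above that of the median probe were kept in each material (24483 probes in each, 17985 in both). This offset understates the changes of dim probes, and fold changes are on that scale unless mean intensities are given.

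Probes were named by the symbols of the array's annotation. Its Entrez identifiers were looked up in a table of human genes for the GRCh38.p14 assembly, which changed 0 symbols and served to match older names in the lists. No coordinates were used because the files name no genome build. Of the probes, 27787 had 1 symbol, 13 had several and 21166 had none, and 18703 genes were named. For a gene with several probes, the probe with the highest mean over the 12 arrays stood for the gene, and other probes are given for ANGPTL4, IGFBP3, WDR4, NOP2, VEGFA and PLOD2. CA9 and other list genes without a named probe (such as SLC16A3, CD63 and PDCD6IP) are not analysed here.

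Hypoxia was compared with normoxia in cells and in exosomes by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted over the probes tested), and the difference of the effects, exosome change minus cell change, in 1 fit of the 12 arrays. The threshold was an adjusted p of 0.05. Cells and exosomes were normalised separately, and material, table and any array run cannot be told apart, so they were compared only by percentiles within arrays and by Spearman's rho. The arrays' shares of listed probes were compared by two-sided exact permutation tests. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

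The named genes followed a rule. It took the 10 largest rises and falls past the threshold whose groups did not overlap, or the 5 smallest p where none passed. For the difference it took the 5 largest each way, without the condition on overlap. It added fixed genes, of which VEGFA, ADM, NDRG1, BNIP3, LOX, IGFBP3, PGK1, SLC2A1, LDHA and PLOD2 are given, CA9 is not analysed here and 1 is not reported here, and up to 4 genes per list with the smallest p. Genes outside the rule are said to have been chosen after their values were seen or are members of a count. The 18 lists, with 525 entries of which 482 had a probe, were HIF-responsive genes, glycolysis and glucose uptake, nuclear-encoded respiratory chain, DNA replication and cell division, amino acid and ER stress response, cholesterol synthesis, and extracellular matrix and remodelling. They went on with angiogenic, growth and inflammatory factors, interferon-stimulated genes, immediate early and heat shock genes, cytosolic ribosomal proteins, replication-dependent histones, vesicle and endosome components, and markers of the glioma line, leukocytes and microglia, neurons, endothelium, and erythroid cells and platelets. Lists of at least 5 tested genes (17) were tested against other genes by camera with a preset correlation of 0.01, adjusted over the lists; fry and camera with an estimated correlation were alternatives. Adjusted over the list alone means that a gene's limma p was adjusted over the genes of its list.

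Whether replicate numbers pair the samples was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. In cells the same-number correlations were 0.451, 0.27 and 0.452, all above the bound of 0.1, so the value with the number as a block is given beside the cell count. In exosomes they were 0.564, 0.0861 and 0.45, and normoxic sample 2 correlated more with hypoxic sample 1 (0.143), so numbers were not taken to pair them. Between materials the same-number correlations were 0.219, 0.13 and 0.364 at normoxia and 0.271, 0.242 and 0.298 at hypoxia.

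The steps were tested on simulated data in which 200 probes of known change, 50 of each size, were added to unchanged ones. For log2 changes of 0.5, 1, 2 and 3, 27, 35, 49 and 49 of 50 were called in the cell design with 4 false calls among 24283. The exosome design gave 41, 47, 50 and 50 with 8 among 24283, and the difference 25, 42, 48 and 50 with 5 among 17785. The simulated changes were added on the log2 scale with the offset, and each probe was drawn independently. The counts thus do not give the power for dim probes, whose changes the offset shrinks, or for arrays that deviate together. Alternatives changed the scaling, the offset, the reading of blanks, the filter, the variance model, array weights, the block, the probes per gene and the arrays included.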

Results

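U87 MG is an established human glioblastoma line, and exosomes are small membrane vesicles that cells release into their medium together with some of their RNA. Total RNA of U87 MG cells kept for 48 hours at 21% oxygen (normoxia) or at 1% oxygen (hypoxia), and of the exosomes collected from their medium, was measured on whole-genome Illumina beadchips. Each of the 4 groups (normoxic cells, hypoxic cells, normoxic exosomes and hypoxic exosomes) had 3 replicates, so 12 arrays were compared. The question was which transcripts respond to low oxygen in the cells, and whether the transcripts carried by exosomes respond with them.

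In the deposited values, exosomal RNA gave a much dimmer picture of the transcriptome than cellular RNA. An intensity of at least 50 was listed for 17.1% ± 0.945 (SD, n = 6) of the 48966 probes in cells and for 4.0% ± 0.302 (SD, n = 6) in exosomes. No test of these shares is given, since each material appears to have been normalised by itself, which sets the share of listed probes above a given intensity. Any value at all was listed for 73.0% ± 4.0 of probes in cells and 65.7% ± 5.23 in exosomes. This difference of 7.27 points did not pass after adjustment (two-sided exact permutation p = 0.0303, Benjamini-Hochberg adjusted p = 0.152 over 5 comparisons). Hypoxia did not separate the listed share within either material (exact permutation p = 0.4 in cells and 0.5 in exosomes), where 3 arrays against 3 cannot give a p below 0.1. The listed intensities of an array summed to between 7012030 and 8166690 in cells and between 961348 and 1175350 in exosomes. Pairs of replicate arrays correlated at r = 0.985 to 0.995 in cells and at r = 0.976 to 0.993 in exosomes across the probes tested. The number of arrays and this dimness limit the precision of the exosome values.

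Hypoxic cells raised a part of the genes known to respond to low oxygen, several of them more than 5-fold. LOX, which cross-links collagen and elastin, rose from a mean intensity of 1351 ± 76.6 (SD, n = 3) to 7689 ± 382. IGFBP3, a secreted carrier of insulin-like growth factors, rose from 1515 ± 327 to 8716 ± 569. HK2, the hexokinase that starts glycolysis in many tumours, rose from 178 ± 30.8 to 1162 ± 246. SLC2A1, the main glucose transporter, rose from 741 ± 127 to 3203 ± 452. Genes that build ribosomes and process RNA, such as NIP7, NOP2, RRS1 and RPP40, stood among the 10 genes with the largest fall. In all, 271 probes passed limma at an adjusted p under 0.05 in the comparison of hypoxic with normoxic cells. Of these, 177 were higher and 94 lower under hypoxia and 87 changed at least 2-fold. They stood for 193 genes of 13231 tested, 120 higher and 73 lower. With the replicate number as a block 16 probes passed, 15 higher and 1 lower, of which 11 were among the 271.

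By the brightest probe of each gene, the largest rise was that of ANGPTL4, a secreted inhibitor of lipoprotein lipase, with a log2 change of 2.96 (SE 0.24, adjusted p = 0.0219) from a mean intensity of 147 ± 65.3 to 1441 ± 187. Its other probes were dim and stayed above the threshold, with log2 changes of 0.37 and 0.41 (adjusted p = 0.148 and 0.0802). IGFBP3 on chromosome 7 followed at 2.50 (SE 0.16, adjusted p = 0.0163), while its other probe rose more, from 773 to 6362 (3.01, adjusted p = 0.0181). LOX on chromosome 5 rose by 2.47 (SE 0.06, adjusted p = 0.000972). ANKRD37, an ankyrin repeat gene, rose from 228 ± 6.77 to 1482 ± 302 (log2 2.44, adjusted p = 0.0163). DEPP1, which lies downstream of FOXO transcription factors, rose from 472 ± 117 to 2743 ± 183 (2.44, adjusted p = 0.0173). The log2 change of HK2 was 2.40 (SE 0.17, adjusted p = 0.0181). MT3, a metal-binding metallothionein of the brain, rose from 168 ± 58.5 to 1088 ± 224 (2.40, adjusted p = 0.0264). ID2, which blocks basic helix-loop-helix transcription factors, rose from 130 ± 28.7 to 879 ± 240 (2.35, adjusted p = 0.0248). TIMP3, an inhibitor of matrix metalloproteinases, rose from 191 ± 89.5 to 975 ± 196 (2.13, adjusted p = 0.0447). A probe named for SLC6A10P, a pseudogene of the creatine transporter gene SLC6A8, rose by 2.26 (adjusted p = 0.0163), and which of these near-identical transcripts it measured is uncertain.

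The deepest fall was that of WDR4, a subunit of a tRNA methyltransferase, from 186 ± 38.1 to 45.7 ± 2.24 (log2 -1.29, SE 0.13, adjusted p = 0.028), although its other probes, both dim, gave -0.04 and 0.01. Factors of the large ribosomal subunit followed. NIP7 fell from 238 ± 51.0 to 71.0 ± 15.4 (-1.25, adjusted p = 0.0386). NOP2, an rRNA methyltransferase, fell from 408 ± 53.7 to 161 ± 30.8 (-1.12, adjusted p = 0.0387), with -0.09 for another, dim probe (adjusted p = 0.561). RRS1 fell from 71.5 ± 17.3 to 9.48 ± 0.661 (-1.02, adjusted p = 0.0295). By mean intensities its fall was deeper than that of WDR4 (7.54-fold against 4.08-fold). RPP40, a protein of the RNase P complex that trims tRNA precursors, fell from 144 ± 19.7 to 49.1 ± 11.4 (-0.97, adjusted p = 0.0379). GART, an enzyme of purine synthesis, fell from 394 ± 36.2 to 183 ± 6.58 (-0.92, SE 0.07, adjusted p = 0.0181). NABP1, which binds single-stranded DNA, fell by 1.12 on the log2 scale, AEN, an apoptosis-enhancing nuclease, by 1.06, NSMCE4A of the SMC5/6 complex by 0.99, and LYSMD2 by 0.94 (adjusted p = 0.0373, 0.0383, 0.031 and 0.031).

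Among the genes fixed before the data were examined, ADM, which encodes the vasodilator adrenomedullin, rose from 3001 ± 528 to 11091 ± 2210 (log2 1.86, SE 0.19, adjusted p = 0.029). NDRG1, a stress-response gene, rose from 839 ± 74.5 to 2255 ± 428 (1.36, SE 0.15, adjusted p = 0.031). SLC2A1 rose by 2.04 (SE 0.15, adjusted p = 0.0181). VEGFA, the chief angiogenic growth factor, had mean intensities of 360 ± 56.2 and 823 ± 196 and missed the threshold with its brightest probe (1.07, adjusted p = 0.0772). A dimmer probe passed it (64.4 against 238, 1.31, adjusted p = 0.0344), but not with the replicate number as a block (adjusted p = 0.0767). BNIP3, a mitochondrial cell death and mitophagy factor, PGK1 and LDHA, glycolytic enzymes, and PLOD2, a collagen lysyl hydroxylase, were already bright at normoxia and missed the threshold, with log2 changes of 0.56, 0.63, 0.24 and 0.75 (adjusted p = 0.132, 0.118, 0.275 and 0.0929). Dimmer probes of PLOD2 gave 1.58 and 1.56 (adjusted p = 0.227 and 0.077).

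**Figure D1:**
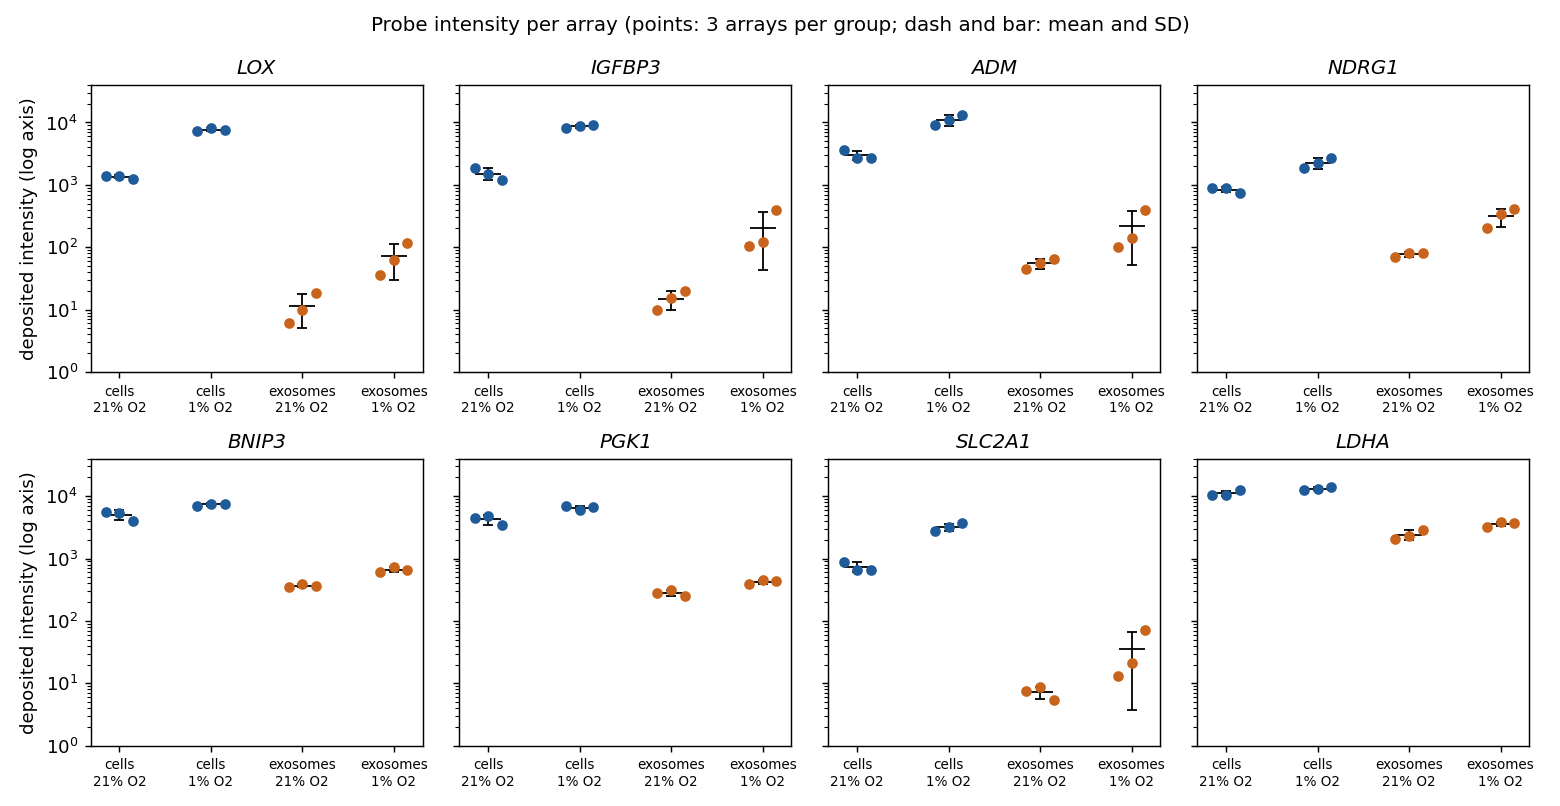
Deposited probe intensity (vertical log axis, arbitrary units) of LOX, IGFBP3, ADM, NDRG1, BNIP3, PGK1, SLC2A1 and LDHA on each of the 12 arrays, by group; points are arrays, and the dash and bar give the mean and SD of 3. Cells and exosomes were normalised separately, so only the steps within a material compare: IGFBP3 went from a mean of 1515 to 8716 in cells and from 14.8 to 207 in exosomes.

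All 35 tested genes of the list of HIF-responsive genes were higher in hypoxic cells, with a median log2 change of 1.03. HIF is the transcription factor that accumulates at low oxygen. Of these, 12 rose (ADM, ANKRD37, CA12, NDRG1, ANGPTL4, LOX, IGFBP3, STC2, ERO1A, INSIG2, BHLHE40 and ZNF395), and 32 passed adjusted over the list alone. With the replicate number as a block only LOX of these 12 passed over all probes (adjusted p = 0.0356, against 0.0586 to 0.101 for the others). ZNF395, a transcription factor, rose from 476 ± 46.4 to 1826 ± 164 (1.84, adjusted p = 0.0163). By camera, the list stood above other genes (adjusted p = 3.86e-26). The call was lost at an adjusted p = 0.458 with an estimated correlation. Glucose uptake and glycolysis genes shifted up too, with 24 of 25 higher, a median of 0.63 and a camera adjusted p = 1.77e-10 (adjusted p = 0.458 with an estimated correlation). HK2, SLC2A1 and PFKFB4, a regulator of glycolytic flux that went from 1852 to 3622, rose, and 18 passed adjusted over the list alone. With the replicate block HK2 passed (adjusted p = 0.0475), and SLC2A1 (0.0683) and PFKFB4 (0.0847) did not. GBE1, the glycogen branching enzyme, had means of 843 and 1836 (1.06, adjusted p = 0.0639).

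Respiratory chain genes of the nucleus stood lower in hypoxic cells, with 28 of 32 lower, a median of -0.14 and a camera adjusted p = 2.16e-06 (adjusted p = 0.835 with an estimated correlation). None of them fell by itself, and 5 were lower adjusted over the list alone (NDUFA8, NDUFB5, NDUFV1, COX8A and ATP5F1A). COX8A of cytochrome oxidase had means of 8085 and 6021. Extracellular matrix genes stood higher, with 29 of 33 higher, a median of 0.33 and a camera adjusted p = 0.00104 (adjusted p = 0.848 with an estimated correlation). The matrix glycoprotein THBS1, dim in both groups, rose from 11.7 ± 1.71 to 41.2 ± 7.70 and the fibronectin receptor subunit ITGA5 from 1369 ± 214 to 2897 ± 392. With TIMP3 these were the 3 that rose, none of which passed with the replicate block (adjusted p = 0.0883, 0.0733 and 0.0847), and 6 passed adjusted over the list alone. The list's shift was 0.146, 0.164 and 0.716 on hypoxic replicates 1, 2 and 3. For the extracellular matrix and remodelling list, cells compared, the median was 0.12 without hypoxic replicate 3 (adjusted p = 0.00407). Genes of DNA replication and cell division stood slightly lower, with 25 of 36 lower, a median of -0.08 and a camera adjusted p = 0.0306 (adjusted p = 0.848 with an estimated correlation). None changed by itself or adjusted over the list alone, and members pointed both ways. The replication licensing gene MCM3 had a log2 change of -0.58 and the thymidine kinase gene TK1 of 0.42 (adjusted p = 0.191 and 0.298). The call of the DNA replication and cell division list, cells compared, was lost without normoxic replicate 1 (median 0.01, adjusted p = 0.342), without normoxic replicate 3 (adjusted p = 0.278) or without hypoxic replicate 3 (adjusted p = 0.73).

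The other lists did not shift as groups in cells, though single members did, none of those named here with the replicate block. In the list of immediate early and heat shock genes, HSPA1B, an inducible HSP70, fell from 1124 ± 97.2 to 646 ± 16.1 (log2 -0.75, adjusted p = 0.0248) and its co-chaperone DNAJB1 from 510 ± 27.3 to 373 ± 11.9 (-0.40, adjusted p = 0.0383). DUSP1 at 1.54 and JUN at 1.11 were higher only adjusted over the list alone. Of the 22 members 8 passed so, 5 higher and 3 lower. The whole list had a median of 0.03 with the test pointing down (adjusted p = 0.376). CAV1, the main protein of caveolae, rose from 4796 ± 260 to 7474 ± 240 (0.64, adjusted p = 0.0228) in the list of vesicle and endosome components. There 4 of 30 passed adjusted over the list alone, the median was 0.02 and the test pointed down (adjusted p = 0.843). The histone gene H2AC18 rose from 577 ± 65.0 to 1176 ± 163 (0.96, adjusted p = 0.0427) among 21 replication-dependent histones (median 0.07, list adjusted p = 0.379, 3 adjusted over the list alone). In the amino acid and ER stress list the median of 21 genes was 0.23 (list adjusted p = 0.123). None changed over all probes, and adjusted over the list alone HSPA5, PPP1R15A and ATF3 were higher and SDF2L1 lower. No gene changed in the lists of cholesterol synthesis (18 genes, median 0.15, adjusted p = 0.199) or of angiogenic, growth and inflammatory factors (30 genes, 0.11, adjusted p = 0.805). The same held for interferon-stimulated genes (25 genes, 0.04, test pointing down, adjusted p = 0.82) and cytosolic ribosomal proteins (68 genes, 0.06, adjusted p = 0.843). In these 4 lists 0 members passed adjusted over the list alone.

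Marker genes of the line and of other cell types were counted as a check on what the cultures held. Of 19 glioma line markers, 13 had an intensity of at least 50 on all 3 normoxic cell arrays and 12 on all 3 hypoxic ones. Their group test gave a median of 0.23 (17 tested, adjusted p = 0.199), with EGFR, PDGFRA and TIMP1 higher and SOX9 lower adjusted over the list alone. Leukocyte and microglia markers at that level were 4 of 16 (CD68, CD74, CSF1R and HLA-DRA), neuron markers 3 of 12 (GAD1, SNAP25 and TUBB3), endothelial markers 1 of 11 (ENG) and erythroid and platelet markers 0 of 10, in both cell groups. The shifts of the leukocyte (median 0.08, adjusted p = 0.653), neuron (0.06, adjusted p = 0.199) and endothelial lists (0.20, adjusted p = 0.265) did not pass. They held 0 members adjusted over the list alone. Only 2 erythroid and platelet genes were tested (median 0.02), too few for a list test.

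The count of the hypoxia effect in cells depended on single arrays and on the scaling. Without normoxic replicate 1, 2 or 3 it was 26, 2 and 2, without hypoxic replicate 1, 2 or 3 it was 586, 2 and 98. Other scalings gave more even splits. They were 487 higher and 435 lower after median centring, 488 and 493 after quantile normalisation over all probes of the cell arrays, and 398 and 382 over all 12 arrays. Of the genes with the 10 largest rises, LOX (adjusted p = 0.0356), DEPP1, HK2 and SLC6A10P (adjusted p = 0.0475 each) passed with the replicate number as a block, and none of the 10 with the largest falls did. Of the 24483 probes tested, 4993 (20.39%) had all 3 arrays of one oxygen level above all 3 of the other, against 10% by chance, 3160 higher and 1833 lower under hypoxia.

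In exosomes no single transcript passed the threshold between hypoxia and normoxia, yet the list of HIF-responsive genes and the glycolysis genes shifted up. Both list calls were lost at an adjusted p = 0.287 with an estimated correlation and at an adjusted p = 0.214 by fry. NDRG1 had mean intensities of 77.2 ± 6.40 (SD, n = 3) in normoxic and 315 ± 100 in hypoxic exosomes, BNIP3 of 369 ± 18.7 and 668 ± 60.7, and ERRFI1, a feedback inhibitor of EGFR, of 80.4 ± 4.67 and 228 ± 39.1. By limma, 0 of 24483 probes had an adjusted p under 0.05, 1393 had an unadjusted p under 0.05, and the lowest adjusted p was 0.12. With a trend in the variance and robust moderation limma called 9 probes, all higher in hypoxic exosomes. Among them were NDRG1 in exosomes (adjusted p = 0.000189), ERRFI1 in exosomes (0.00257) and ZNF395 in exosomes (0.0093). With an offset of 16 limma called ZNF395 alone, with an intensity filter of 16 it called 5 probes, all higher, and without hypoxic replicate 1 it called ERRFI1 alone.

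The genes with the smallest p all missed the threshold. They were ZNF395 (36.8 ± 2.88 against 100.0 ± 9.79, log2 0.79, SE 0.05, adjusted p = 0.12), BNIP3 (0.78, SE 0.07, adjusted p = 0.256) and RFTN1, a lipid raft protein gene (26.3 ± 0.991 against 13.4 ± 1.25, -0.27, adjusted p = 0.256), then ERRFI1 (1.08, SE 0.10, adjusted p = 0.269) and DYNLT1, a dynein light chain gene (120 ± 8.78 against 85.0 ± 2.25, -0.34, adjusted p = 0.627). NDRG1 gave 1.48 (SE 0.20, adjusted p = 0.627). IGFBP3 had means of 14.8 ± 4.98 and 207 ± 163 (1.81, adjusted p = 0.838), and LOX of 11.6 ± 6.49 and 72.5 ± 42.1 (0.94, adjusted p = 0.838). ADM had means of 55.1 ± 10.0 and 215 ± 163 (1.17, adjusted p = 0.862). On all 3 hypoxic arrays NDRG1, IGFBP3, LOX and ADM lay above all 3 normoxic ones. LDHA went from 2419 ± 430 to 3608 ± 323 (0.58, adjusted p = 0.838), PGK1 from 284 ± 30.8 to 429 ± 33.1 (0.52, adjusted p = 0.69) and PLOD2 from 66.7 ± 12.3 to 185 ± 91.2 (0.95, adjusted p = 0.838). SLC2A1 (7.24 against 35.2, 0.51) and VEGFA (7.97 against 13.4, 0.12) were dim in both groups (adjusted p = 0.866 and 0.901). Over the probes tested, 2496 (10.19%) separated the 3 hypoxic from the 3 normoxic arrays, close to the 10% of chance, 818 higher and 1678 lower.

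Of 30 HIF-responsive genes tested in exosomes, 28 were higher under hypoxia, with a median of 0.25 and a camera adjusted p = 2.39e-26 (adjusted p = 0.287 with an estimated correlation). None passed over all probes, and 16 passed adjusted over the list alone, 15 of them higher. Besides genes named above, PPP1R3C, a regulator of glycogen synthesis, was among them with means of 169 ± 29.4 and 496 ± 125. That count of 15 was 4, 5 and 5 without normoxic replicate 1, 2 or 3 and 6 without hypoxic replicate 2. Glycolysis genes were higher in 23 of 25 cases, with a median of 0.31 and a camera adjusted p = 2.6e-20 (adjusted p = 0.287 with an estimated correlation). Of them 7 passed adjusted over the list alone (PFKP, PFKFB4, ALDOA, PGK1, ENO2, LDHA and GBE1). The enolase ENO2 had means of 108 and 183. The amino acid and ER stress list was higher in 16 of 17 genes, with a median of 0.16 and a camera adjusted p = 1.96e-06 (adjusted p = 0.498 with an estimated correlation). From the normoxic mean, the list's shift was -0.0424, 0.217 and 0.312 on hypoxic replicates 1, 2 and 3, so replicate 1 showed no rise. With 0 passing adjusted over the list alone, its leading members were the stress transcription factors ATF3 (12 against 32.0) and DDIT3 (38.3 against 65.1).

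Respiratory chain and ribosomal protein genes stood lower in hypoxic exosomes, as did brighter probes in general: of 1984 exosome probes with a mean intensity of at least 50, 25% were higher, with a median change of -0.10. The respiratory chain genes were lower in 29 of 32 cases, with a median of -0.21 and a camera adjusted p = 6.63e-05 (adjusted p = 0.915 with an estimated correlation). From the normoxic mean, their shift was -0.24, -0.0391 and -0.297 on hypoxic replicates 1, 2 and 3. On normoxic replicates 1, 2 and 3 it was -0.121, -0.0417 and 0.15. The complex I gene NDUFA1 (948 ± 72.1 against 727 ± 36.2) was the 1 member that passed adjusted over the list alone. Cytosolic ribosomal proteins were lower in 62 of 67 cases, with a median of -0.10, a camera adjusted p = 0.000791 (adjusted p = 0.965 with an estimated correlation) and 0 adjusted over the list alone. RPS3 had means of 1946 ± 134 and 1573 ± 98.4. The call ended without normoxic replicate 3 (adjusted p = 0.57) or hypoxic replicate 1 (adjusted p = 0.356). Extracellular matrix genes were higher in 19 of 26 cases, with a median of 0.05, a camera adjusted p = 0.000791 (adjusted p = 0.852 with an estimated correlation) and 0 adjusted over the list alone. Without hypoxic replicate 3 their median was -0.01 (adjusted p = 0.991), so that 1 array carried the matrix call. On that array the collagen gene COL1A2 was at 84.5 and the matrix protein gene TGFBI at 1924, against 8.3 and 14.8 and 362 and 680 on the other hypoxic exosome arrays. These genes were chosen after their values were seen.

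The remaining lists did not pass in exosomes, and none of their genes passed over all probes. Their medians and adjusted p were -0.04 and 0.958 for DNA replication and cell division (33 genes) and -0.01 and 0.815 for cholesterol synthesis (17 genes). They were -0.02 and 0.958 for angiogenic, growth and inflammatory factors (21 genes), and 0.02 and 0.186 for glioma line markers (15 genes). In 5 more lists with a median within 0.03 of 0 the sign of the median and of the test, which pointed up, differed. They were interferon-stimulated genes (22 genes, adjusted p = 0.958), immediate early and heat shock genes (22 genes, 0.618), histones (17 genes, 0.618), vesicle and endosome components (30 genes, 0.666) and neuron markers (7 genes, 0.958). Leukocyte (6 genes, 0.404) and endothelial markers (6 genes, 0.826) had medians of 0.00 and -0.01. In all of these lists 0 members passed adjusted over the list alone. Of the 2 erythroid and platelet genes tested (median -0.05), ALAS2 was lower adjusted over the list alone, at 4.35 against 1.5, which is near background. Without hypoxic replicate 3 the DNA replication and cell division list, exosomes compared, turned to higher, with a median of 0.05 (adjusted p = 0.000411).

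**Figure D2:**
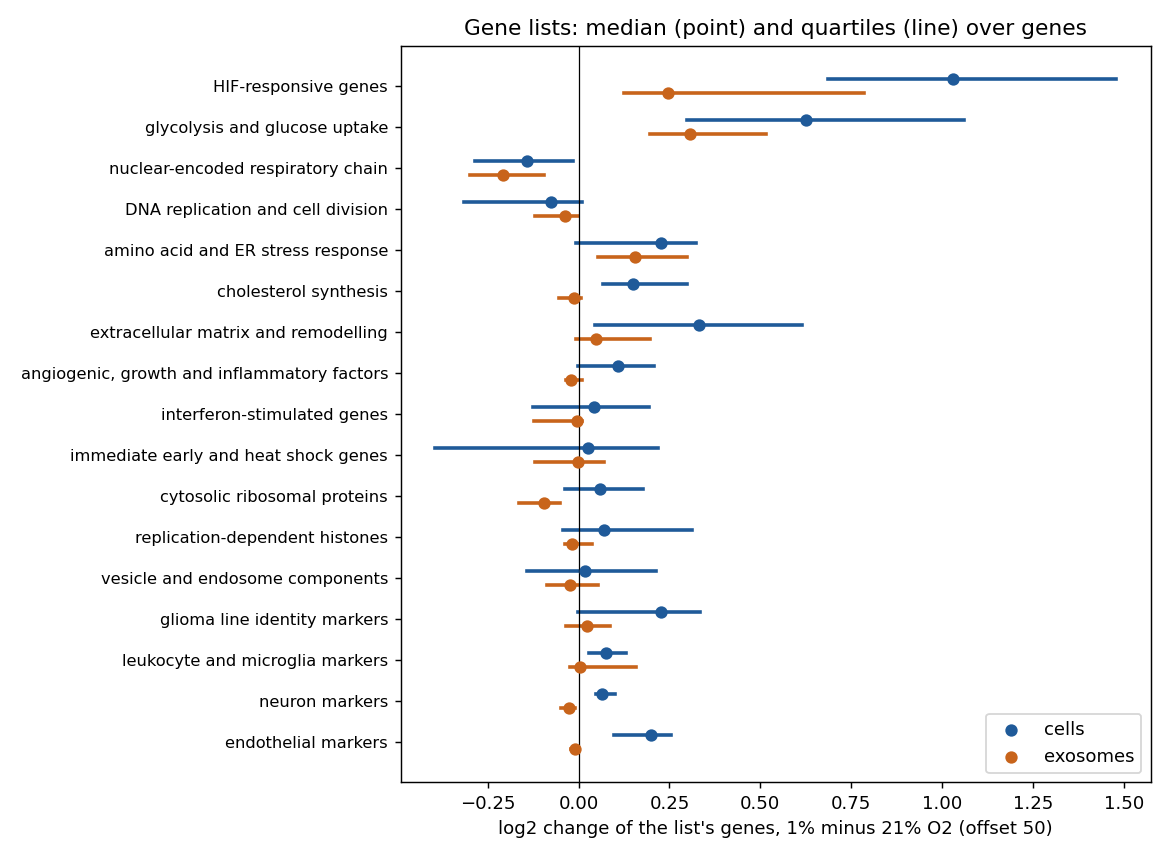
Median (point) and quartiles (line) over the genes of 17 lists of the log2 change from 21% to 1% oxygen (horizontal axis, offset 50) in cells and in exosomes. The HIF-responsive genes lie farthest to the right in cells, with a median of 1.03 against 0.25 in exosomes.

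The exosome changes followed those of the cells in direction for the genes that moved most, which was the question of the joint comparison. Of 108 genes that rose in cells and were tested in exosomes, 79 were higher in hypoxic exosomes, against 33.71% of all 10394 genes tested in both (Fisher's exact p = 4.77e-17). Of 73 that fell, 64 were lower, against 66.29% of all (Fisher's exact p = 5.03e-05). As a group the genes that rose in cells stood higher in exosomes (median 0.05, camera adjusted p = 3.14e-25, and adjusted p = 0.0158 with an estimated correlation). Of them 19 passed adjusted over that group alone, led by ZNF395, ERRFI1, NDRG1, the cytoskeletal gene DPYSL4 and DEPP1. Those that fell stood lower (median -0.09, adjusted p = 2.36e-07, and adjusted p = 0.317 with an estimated correlation), with 0 adjusted over that group alone. Across genes, which are not independent replicates, the log2 changes in the 2 materials correlated at Pearson r = 0.499 and Spearman rho = 0.388 with a covariance of 0.0158. The value of r was 0.303 without hypoxic exosome replicate 3. The comparisons share no arrays, but same-numbered cell and exosome arrays deviated together (r = 0.219, 0.13 and 0.364 at normoxia and 0.271, 0.242 and 0.298 at hypoxia). The values for independent lists leave this out, so that neither the correlation nor the overlaps have a baseline of 0 shared signal. Genes with an unadjusted p under 0.05 in exosomes overlapped those that rose in cells in 37 cases against 1.38 for independent lists (Fisher's exact p = 2.27e-44), and those that fell in 12 against 4.49 (p = 0.00152). Where exosome probes had a mean intensity of at least 50 (1471 genes), r was 0.699.

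**Figure D3:**
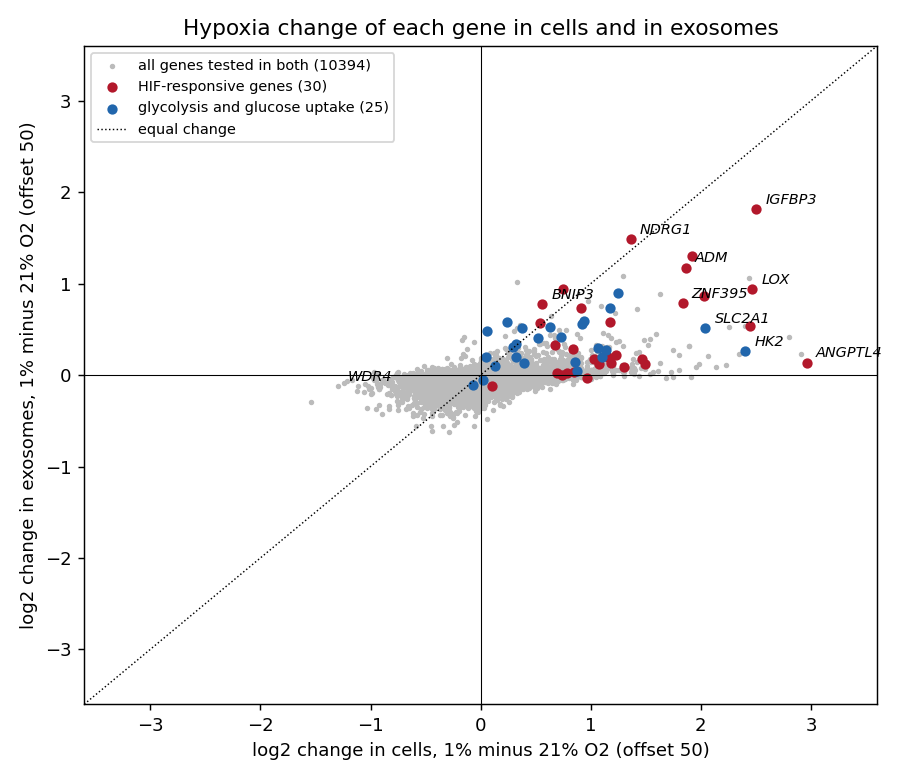
Log2 change from 21% to 1% oxygen (offset 50) of each of 10394 genes in cells (horizontal axis) and exosomes (vertical axis), with HIF-responsive genes in red, glycolysis genes in blue and the line of equal change dotted. Most genes with large changes in cells lie below the line, such as ANGPTL4 at 2.96 in cells and 0.13 in exosomes, while NDRG1 lies near it at 1.36 and 1.48. In exosomes ANGPTL4 was near background (means of 3.53 and 8.82), where the offset presses changes together.

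On this scale the response was smaller in exosomes for many genes. The test of the difference, the exosome change minus the cell change, called 401 probes of 17985. Of these, 107 had a higher and 294 a lower change in exosomes, 92 by at least 2-fold, and they stood for 277 genes. ANGPTL4 differed by -2.83 (SE 0.27, adjusted p = 0.00201), HK2 by -2.14 (SE 0.22, adjusted p = 0.00201) and ID2 by -2.12 (SE 0.25, adjusted p = 0.00335). IL1A, which encodes the cytokine interleukin-1 alpha, differed by -2.68 (SE 0.52, adjusted p = 0.0307) and CPA4, a carboxypeptidase gene, by -2.39 (SE 0.48, adjusted p = 0.0365). The opposite sign was that of genes that fell in cells. WDR4 differed by 1.17 (adjusted p = 0.00494), NIP7 by 1.16 (0.022), RPP40 by 1.00 (0.0255), NABP1 by 1.00 (0.00888) and RRS1 by 0.90 (0.00567). Of the genes fixed beforehand, LOX (-1.52, adjusted p = 0.0223) and SLC2A1 (-1.53, adjusted p = 0.0353) differed. With the replicate number as a block SLC2A1 and RPP40 missed the threshold (adjusted p = 0.0519 each). By mean intensities LOX rose 6.2-fold in exosomes and 5.7-fold in cells, and SLC2A1 4.9-fold and 4.3-fold. ANGPTL4 (2.5-fold and 9.8-fold) and HK2 (2.7-fold and 6.5-fold) rose less in exosomes by this measure too. The normoxic exosome means of LOX (11.6) and SLC2A1 (7.24) lie near background, so whether these 2 changed less than in cells without the offset is open. IGFBP3 (-0.69, adjusted p = 0.558), ADM (-0.69, 0.564), NDRG1 (0.12, 0.895) and BNIP3 (0.21, 0.601) did not pass, and neither did PGK1 (-0.10, 0.849), LDHA (0.34, 0.407), PLOD2 (0.20, 0.85) and VEGFA (-0.95, 0.0661; 0.0181 with that block). Of their dimmer probes, 1 of VEGFA (-1.31, adjusted p = 0.00478) and 1 of PLOD2 (-1.41, 0.0479) passed, the latter not with that block (0.0731). Another of PLOD2 (-1.54, 0.208) and that of IGFBP3 (-1.80, 0.0757) did not pass.

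The HIF-responsive genes were the 1 list of 17 called for this difference (30 genes, median -0.79, quartiles -1.05 to -0.57, camera adjusted p = 4.09e-12; adjusted p = 0.758 with an estimated correlation). Of the 30, 26 had a lower change in exosomes, of which 9 passed over all probes and 19 adjusted over the list alone. The glycolysis list did not pass (median -0.26, adjusted p = 0.223; 7 adjusted over the list alone), though HK2 and SLC2A1 did. In lists that did not pass, TIMP3 (-2.05, adjusted p = 0.00941), H2AC18 (-0.82, 0.0217) and SDC4, a syndecan gene (-1.10, 0.0388), had lower changes in exosomes, and HSPA1B (0.79, 0.0292) and DNAJB1 (0.31, 0.0328) higher ones. With the replicate block SDC4 (0.0519) and HSPA1B (0.0527) missed the threshold. Most transcripts that differed were dim in exosomes, where the offset shrinks a change. With a mean intensity of at least 50 in both materials 0 probes passed by limma (88 at an unadjusted p under 0.05) and the list's median was -0.39 (adjusted p = 0.229). Adding an offset of 16 brought it to 0.06 (adjusted p = 0.729; 0 probes, 64 unadjusted). Some members, such as IGFBP3 and ZNF395, passed that mean only through their hypoxic exosome values. The count of the difference of the hypoxia effect between exosomes and cells was 1806 without hypoxic cell replicate 1. It was 164, 149 and 177 without normoxic exosome replicate 1, 2 or 3 and 163, 178 and 218 without hypoxic exosome replicate 1, 2 or 3. It split into 239 higher and 397 lower after median centring, 455 and 439 after quantile normalisation over all probes of a material, and 0 and 3 over all 12 arrays.

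Exosomes carried transcripts in an order close to that of their cells. Across 14423 genes, ranks within arrays, averaged over the arrays of a group, correlated between exosomes and cells at Spearman rho = 0.815 at normoxia and 0.789 at hypoxia. Hypoxic cells and normoxic exosomes correlated at 0.803, and hypoxic and normoxic arrays of the same material at 0.983 in cells and 0.909 in exosomes. Probes differ in affinity, which raises such correlations over the same probes and enters the percentiles of a list. Of the lists, ribosomal protein genes had the highest median percentile in both, 99.3 ± 0.0473 (SD, n = 3) in normoxic exosomes and 98.9 ± 0.185 in normoxic cells. HIF-responsive genes went from the 70.5 ± 3.04 percentile to 81.9 ± 3.56 in exosomes and from 78.8 ± 1.02 to 91.8 ± 0.224 in cells. Extracellular matrix genes ranked lower in normoxic exosomes (53.7 ± 11) than in normoxic cells (79.5 ± 2.95), and so did vesicle and endosome components (87.7 ± 0.869 against 91.6 ± 0.529). Of the latter, 11 of 30 genes, among them ANXA2, CAV1, CD81 and TSG101, reached an intensity of 50 on all 3 normoxic exosome arrays and all 30 on the cell arrays. That intensity was reached by a mean of 4.10% of all probes on normoxic exosome arrays and 16.7% on normoxic cell arrays. Of the glioma line markers, CD44, LGALS1, S100A10, S100A11, S100A6, TIMP1 and VIM reached it in exosomes. CD68 and TUBB3 of the leukocyte and neuron markers did too, and 0 of the endothelial and of the erythroid and platelet markers. Material, table and any array run went together, so no probe was tested between exosomes and cells.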

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

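The tests of dim signal and offset together, the tests on normalisation over listed values and those on hypoxic exosome replicate 3 were chosen only after the result was seen, and the criteria for reading the HIF tests were changed after their values were seen.

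These results stand here because the test of the difference between the hypoxia effects in exosomes and in cells passed for them. The HIF-responsive genes had a median difference, exosome minus cell log2 change, of -0.791, and this call was lost at an estimated correlation (adjusted p = 0.758). Among the genes, WDR4 differed by 1.17, NIP7 by 1.16, RPP40 by 1.00, NABP1 by 0.999 and RRS1 by 0.902, after a fall in cells. In exosomes, near background, the means of WDR4 (13.3 against 8.11), NABP1 (12.2 against 7.36), RRS1 (10.4 against 5.57) and NIP7 (18.2 against 14.5) were lower at hypoxia too. That of RPP40 was higher (13.2 against 14.9). None of these passed in exosomes (limma adjusted p = 0.863 to 0.99), where the offset presses changes together. ANGPTL4 differed by -2.83, IL1A by -2.68, CPA4 by -2.39, HK2 by -2.14, ID2 by -2.12, LOX by -1.52 and SLC2A1 by -1.53, with a smaller change in exosomes on the scale with an offset of 50. With the replicate number as a block RPP40 and SLC2A1 missed the threshold (adjusted p = 0.0519 each). LOX and SLC2A1 had normoxic exosome means of 11.6 and 7.24, near background, so their folds cannot be compared with those in cells. IL1A and CPA4 were near background in exosomes too: IL1A had mean intensities of 82.4 ± 50.1 and 967 ± 476 in cells against 2.33 and 11.6 in exosomes, and CPA4 of 406 ± 244 and 2975 ± 1001 against 6.49 and 27.1. In cells alone, IL1A and CPA4 missed the threshold (adjusted p = 0.0666 and 0.0532) and passed with the replicate number as a block (adjusted p = 0.0475 each).

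The splits did not exclude chance for the count of the difference, and they cannot decide on it. Of 100 drawn of the 200 splits of the arrays within materials, 9 gave at least as many probes, the real one included. The real split called 401 and the highest other 964. The 8 other splits as large all kept the study's division of the cell arrays. They thus hold the whole cell effect and are no measure of chance for the difference. With the cell arrays divided otherwise, the highest count was 8. The count thus rests on how the cell arrays are divided. Why other divisions of the exosome arrays called more was not tested. For cells the splits are too few for a share under 0.05: the real split called 271 probes, 1 of 10 splits called as many (the real one), and the highest other called 0. For exosomes the splits are too few as well: the real split called 0 and the highest other 0, so that all 10 called as many.

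For the smaller shift of the HIF-responsive genes in exosomes, the median difference with an offset of 1 in place of 50 was -0.362 (quartiles -0.776 to 0.00), and over the 10 members with a mean intensity of at least 50 in both materials it was -0.386 (quartiles -0.671 to 0.10). Both lie below the bound of -0.1 set beforehand, but that bound asked each cause to explain the shift alone, while a dim probe is pressed together by the offset and by background at the same time. For these 10 with an offset of 1 the median was 0.19, but CA12, IGFBP3 and ZNF395 are among them only through their hypoxic values, so that this decides nothing. For the 7 members with a mean of at least 50 at normoxia in each material, it was 0.242 with an offset of 1 (quartiles -0.02 to 0.42) and 0.0305 with an offset of 50. Dim signal together with the offset may thus explain why the list as a whole shifted less, though 7 members are few. These 7 also changed less in cells, with a median of 0.921 against 1.25 for all 30 members (offset 1). The test does not set this apart from a fuller response in exosomes. For the 20 dimmer members, at -0.662 with an offset of 1 (18 lower), a smaller response of exosomal RNA and a signal too near background cannot be told apart, and the biological difference of material stays open.

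Among exosome probes with a mean intensity of at least 50, 25% of 1984 were higher under hypoxia, with a median change of -0.10. Quantile normalisation over all probes brought the share to 42.1%, short of the 45% that would have fitted the deposited normalisation as the cause and above the 40% that would have spoken against it. Leaving out hypoxic replicate 3 brought it to 40.3%, the highest with 1 hypoxic array left out (32.9% without replicate 1 and 14.9% without replicate 2). A part of the general decrease could thus come from the normalisation or from 1 array, and an effect of oxygen stays open.

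Hypoxic exosome replicate 3 deviated from the other arrays of its group. Across genes its deviation correlated at r = 0.491 with the percentile in cells minus that in exosomes, against -0.18 to 0.123 on the normoxic exosome arrays. A larger part of cell RNA in that preparation may thus explain it. By ranks over all genes, however, this array was hardly closer to the mean of hypoxic cells (rho = 0.778) than hypoxic replicates 1 (0.771) and 2 (0.753). Its deviation also correlated at r = 0.499 with that of hypoxic cell replicate 3 over 2113 genes, where the other same-numbered pairs of an exosome and a cell array gave 0.215 to 0.536, so a difference of the culture shared by cells and exosomes is a candidate explanation as well. The tests do not separate these, and genes are not independent replicates.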

How the results depend on the processing

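The offsets on the value table, blanks as missing, both quantile normalisations and the filters at 16 and at a mean of 50 were chosen only after the data were seen. So were leaving out both replicate 3 arrays and the rank correlations over genes listed on all 12 arrays. Unless said, the cause was not tested.

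The count of the hypoxia effect in cells, 271, was 922 after median centring, 981 and 780 after quantile normalisation over all probes of the cell arrays and of all 12. It was 544 with an offset of 16, 761 with a filter at 16, 1607 with array weights, 821 with trend and robust moderation and 2358 with all 12 arrays sharing the spread. It was 1 with no filter and 2 without both replicate 3 arrays, which leaves 2 arrays per group, and 2 to 586 with 1 array left out. Of the 271, 256 were among the 922, 238 among the 981, 203 among the 821, 265 among the 2358 and all 271 among the 1607. With the replicate number as a block it was 16, with 11 shared; the block uses up residual degrees of freedom.

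The count of the hypoxia effect in exosomes, 0, became 9 with trend and robust moderation, 1 with an offset of 16 and 5 with a filter at 16, all higher, and ran from 0 to 1 with 1 array left out. It was 0 by limma under the others run, the replicate block included (1595 at an unadjusted p under 0.05, lowest adjusted p = 0.135). The block called 1 more list, the glioma line identity markers list, exosomes compared (0.0228, adjusted p = 0.00884).

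The count of the difference of the hypoxia effect between exosomes and cells, 401, became 636 after median centring, 894 and 3 after the quantile normalisations. It was 207 and 6 with offsets of 16 and 1, 19 with a filter at 16, 161 without both replicate 3 arrays, and 0 with a mean of at least 50 in both materials, with an offset of 50 or of 16. With 1 array left out it ran from 149 to 1806, and with the replicate block it was 346, of which 293 were shared.

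The agreement of the hypoxia effects across genes, r = 0.499, was 0.235 with an offset of 1, 0.649 with a filter at 16, 0.7 and 0.711 with a mean of at least 50 at offsets of 50 and 16. It was 0.699 where the exosome mean was at least 50, 0.626 over the genes called in cells and 0.313 without both replicate 3 arrays, and 0.303 to 0.509 with 1 array left out. Dim exosome probes were fewer under the settings with a higher value. The rank correlation of exosomes with cells was 0.86 at normoxia, 0.851 at hypoxia and 0.828 for hypoxic cells with normoxic exosomes over genes listed on all 12 arrays, and 0.83 for the last with no filter. With 1 array left out these ran 0.794 to 0.819, 0.771 to 0.792 and 0.781 to 0.807.

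The HIF-responsive genes kept their direction in cells and in exosomes under every setting run, with medians of 0.866 to 1.14 and 0.182 to 0.327 with 1 array left out. With an estimated correlation the medians of 1.03 in cells, 0.247 in exosomes and -0.791 for the difference no longer passed (adjusted p = 0.458, 0.287 and 0.758). By fry the HIF list passed in cells (adjusted p = 0.00771) and for the difference (0.0179), but not in exosomes (0.214). Of the other lists that camera called in cells, fry kept glycolysis (0.0206). It lost the respiratory chain, the extracellular matrix (0.282 each) and DNA replication (0.708). No list passed by fry in exosomes. For the HIF-responsive genes list, difference compared, the median was -0.972 to -0.677 with 1 array left out. It no longer passed with an offset of 1 (-0.362, adjusted p = 0.441) or a mean of at least 50 (-0.386, 0.229), and turned to 0.0553 (0.729) with the latter and an offset of 16.

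The DNA replication and cell division list, cells compared, reversed without both replicate 3 arrays (0.0468) and ran from -0.244 to 0.00644 (without normoxic replicate 1) with 1 array left out. The DNA replication and cell division list, exosomes compared, reversed without both replicate 3 arrays (0.0706) and ran from -0.119 to 0.0462 (without hypoxic replicate 3). The extracellular matrix and remodelling list, exosomes compared, ran from -0.00737 (without hypoxic replicate 3) to 0.0703. The difference of 7.27 points in the listed share (probes detected per array) passed before adjustment. It ran from 5.98 to 8.5 with 1 array left out and had a p above 0.05 without normoxic exosome replicate 1 (6.99, exact p = 0.0519), hypoxic exosome replicate 1 (6.22, 0.0563) or 3 (6.02, 0.0563), or hypoxic cell replicate 2 (6.68, 0.0563) or 3 (5.98, 0.0584). The median change over the probes tested was 0.0215 in cells, -0.00751 in exosomes and -0.0476 for the difference. It lay more than 0.1 from 0 with an offset of 1 (0.105 in cells, -0.227 for the difference) and of 16 (-0.103 for the difference). The same held with a mean of at least 50 (-0.102 in exosomes), and with that mean and an offset of 16 (-0.129 in exosomes, -0.105 for the difference).

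Of 532 values of named genes in cells under alternatives, 349 kept their side of the threshold, 165 lost and 18 gained it; of 264 in exosomes, 255 kept it and 9 gained it. None of these changed sign where the main or the alternative value passed the threshold. For all other values, as for most in exosomes, a change of sign was not counted. Not run were the alternatives that need the scanner tables (neqc with an offset of 50 or over all 12 arrays, filters on detection p), a chip block, since the files give no chip, and tests of probes between materials with their centring and block. Signal over background limits the exosome values.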

Other observations

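The gene lists and families here were written only after the result that led to them was seen, with the genes already seen left out, the genes and ranks given per array were chosen after their values were seen, and the reading of the exosome test of ribosome assembly was settled after its value was seen.

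Ribosome assembly genes stood among the genes that fell in hypoxic cells, so other ribosome biogenesis factors were tested as a group. Of 80 tested in cells, 67 were lower, with a median of -0.22 (quartiles -0.478 to -0.05) and a camera p = 1.51e-14 (p = 0.0826 with an estimated correlation). RRP7A (-0.71, adjusted p = 0.0453), RRP15 (-0.55, 0.0477), NOLC1 (-0.54, 0.0445) and RRP9 (-0.38, 0.031), which act in the processing of ribosomal RNA, fell, and 21 fell adjusted over the list alone. With the replicate number as a block these 4 missed the threshold (adjusted p = 0.104, 0.0805, 0.0847 and 0.0889). After quantile normalisation over all probes the median of the list was -0.31. In exosomes 60 of 73 were lower with a median of -0.04, and the test missed its threshold (p = 0.0577, and 0.685 with an estimated correlation), as did the bound set beforehand, which leaves open whether they were lower. Hypoxic U87 MG cells may thus lower the transcripts of ribosome assembly as a program, though the call in cells was lost with an estimated correlation. The list of ribosomal protein genes did not pass in cells (camera adjusted p = 0.843), which does not show that they were unchanged.

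Some transcripts ranked far higher or lower in exosomes than in cells on all arrays. KIF1C, a kinesin gene, stood at a mean percentile of 96.9 in exosomes and 48.4 in cells, NET1, a RhoA exchange factor gene, at 99.3 and 72.2, and RAB13, a small GTPase gene, at 98.9 and 65.2. TRAK2, a mitochondrial transport adaptor gene, stood at 99.9 and 86.7, NUDT16 at 97.1 and 50.2, and PLEKHA4 at 96.9 and 57.9. Genes of secreted and membrane proteins ranked higher in exosomes too, such as the growth factor GDF11 (97.8 and 68.8) and the receptor DDR2 (98.5 and 88.5). On the other side were NRP1 (48.2 and 89.6), the ER chaperone HSPA5 (57.3 and 92.0), the lysosomal LAMP2 (64.0 and 93.3) and the receptor PDGFRB (67.8 and 94.8). Membrane and secreted proteins among the latter led to a test on families of genes with a mean cell intensity of at least 500.

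In 81 genes of secreted and membrane families the median percentile in exosomes minus cells was -7.65 (87.7% lower), against 0.79 in 111 genes of cytosolic and nuclear families (30.6% lower; permutation p = 1e-05, the smallest that the resamples can give). For 7 mitochondrial carriers, membrane proteins made in the cytosol, it was 0.243. This lay above the secreted and membrane families (permutation p = 0.00046). The test against the cytosolic and nuclear families did not pass (permutation p = 0.162), which with 7 genes does not show that they are alike. As a group these carriers thus did not rank lower in exosomes, but 7 genes of 1 family do not speak for other membrane proteins. In these families transcripts translated at the endoplasmic reticulum ranked lower in exosomes. Whether they are held back from exosomes was not tested. The difference between the families was -11.8, -9.86 and -10.3 on the normoxic exosome arrays, -11.9, -11.5 and -5.54 on the hypoxic ones, and between -2.68 and 0.416 on the cell arrays. Percentiles at the dim end of exosome arrays are imprecise, which this test does not remove.

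A few genes differed between arrays of the same group by far more than with oxygen. NBPF9, of a multicopy family whose copies a probe may not separate, had intensities of 2691, 2677 and 367 in normoxic cell replicates 1, 2 and 3 and of 2329, 2189 and 403 in hypoxic ones. In exosomes it had 3036, 2957 and 88.4 at normoxia and 2522, 2687 and 51.5 at hypoxia. Its change with oxygen missed the threshold of limma without the replicate block in cells (adjusted p = 0.975) and in exosomes (adjusted p = 0.993). IL1B, an inflammatory cytokine gene, had 7984, 3106 and 395 and then 6871, 3015 and 756 in cells, and 1003, 406 and 17.9 and then 919, 335 and 37.8 in exosomes. PI3, an elastase inhibitor gene, had 7175, 2499 and 381 and then 13097, 7261 and 1521 in cells. In exosomes it had 146, 140 and 14.3 and then 474, 215 and 27.9. By replicate number PI3 was higher under hypoxia each time. In the fit without the replicate block its change missed the threshold (limma adjusted p = 0.704 in cells and 0.946 in exosomes). That fit counts the spread between replicate numbers as error, so these p-values do not measure the change within a number. The correlation of r = 0.499 between the deviations of hypoxic exosome and cell replicate 3 includes such genes.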
